A study of Bos taurus with 6 samples.

How the data were processed

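The series is the first test of a bovine cDNA microarray, a glass array of spotted complementary DNAs read in 2 colours. Total RNA of adrenal gland was hybridised against adrenal, and RNA of lymph tissue against lymph, so both channels of an array held the same kind of tissue (a self-self hybridisation). GEO lists 3 arrays for each tissue, numbered 1 to 3. The labels do not say whether the arrays came from separate animals or from repeated labelling of 1 RNA, so the p-values measure the spread between these arrays, which may be technical. The kind of lymph tissue is not given in the sources used here.

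The deposited table held 1 value per feature and array for 19200 features. From the values, these were log ratios of the 2 channels, with medians between -0.011 and 0.0017 and no exact zeros. The scanner, background correction, normalisation, base of the logarithm, dye of the numerator and dye orientation of each array were not given in the sources used here. The means lay between 0.00024 and 0.0027, on each array nearer 0 than the median. Whether the log ratios were centred before deposit was not given in the sources used here, and these values alone do not settle it. Values are therefore given in deposited log units, above or below 0, with no statement on which channel was brighter. A fold is given only where the assumed base is named.

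The columns of adrenal array 2 and lymph array 3 were identical in all 19200 rows, empty cells included. They were taken as 1 hybridisation listed under both tissues, counted once, and called the shared array. Its tissue is unknown, so it entered no tissue group. This left 2 adrenal arrays (1 and 3), 2 lymph arrays (1 and 2) and 5 distinct arrays. The design fixed before the data were examined had used all 6 columns, 3 per tissue, and that fit is given as an alternative.

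Gene names came from GEO's platform annotation. An entry existed for 12854 features, of which 12630 had 1 gene symbol and 224 had several. The other 6346 had none and are unnamed here. The gene numbers of 12497 single-gene features were found in the RefSeq gene table of assembly ARS-UCD2.0, used for names only, and 0 symbols changed. These features covered 8397 genes, of which 3167 had at least 2 features. The feature numbers followed the order of the sequence accessions, and the print layout was not used here.

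Each array was centred on its median. limma 3.58.1 in R 4.3.3 (lmFit and eBayes) gave 4 two-sided tests with Benjamini-Hochberg adjustment at 0.05, which were adrenal against 0, lymph against 0, lymph minus adrenal, and the average against 0. The first 3 used 4 arrays, with 1 coefficient per tissue and a common spread on 2 residual degrees of freedom. The average used the 5 distinct arrays with 1 coefficient. Each SE given with these tests is limma's moderated one, which draws the spread of a feature towards that of all features. Features needed at least 2 values per tissue, which 18941 met. On simulated data with the observed spread, 200 of 18941 features were shifted in each of 5 simulations. A shift of 0.25 log units was recovered for 0% of features in adrenal, the difference and the average (lymph was not simulated). A shift of 0.5 was recovered for 0.2% of features in adrenal, 0% in the difference and 96% in the average. A shift of 1 log unit was recovered for 99.4%, 87% and 99.9%. The simulated noise was drawn independently for each array, so it lacked the weak correlation between the real arrays described below. The number of arrays limits the precision.

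The rule for named genes took the 12 largest values per direction past the threshold. Where fewer than 5 passed, it took the 5 single-gene features with the smallest unadjusted p, given as values, and at most 2 unnamed features by number. The 13 gene lists were fixed before the data were examined. They were tested on gene means with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry. Camera compares a list with all other genes. With an estimated correlation it also takes its degrees of freedom from the residuals, of which there were 2 here, or 4 for the average. Fry tests whether a list moves on balance in 1 direction. Spreads per array were compared by an exact two-sided permutation test, and correlations between arrays by the 3 splits of the 4 tissue arrays into pairs. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.

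Alternatives were other centring and scaling, other handling of empty cells, each array left out, other spread estimates, stricter thresholds, features averaged per gene, centring in runs of 400 feature numbers, and the replicate number as a block. The fit on all 6 columns, planned as the main fit, became an alternative once the identical columns were seen. Chosen after seeing the data were the assignments of the shared array to either tissue, with and without the filter on empty cells. Other bases of the logarithm and lists tested on single features were also chosen then.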

Results

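A bovine cDNA array of 19200 features was hybridised with adrenal RNA in both channels or with lymph RNA in both channels. Because both channels held the same tissue, the comparisons show how far log ratios left 0 without a difference in tissue. The adrenal gland joins a steroid-producing cortex to a medulla of catecholamine-producing chromaffin cells, and lymph tissue is rich in lymphocytes. Adrenal array 2 and lymph array 3 held identical values in all 19200 rows and were counted as 1 array of unknown tissue, the shared array. The comparisons therefore rest on 2 adrenal arrays, 2 lymph arrays and 5 distinct arrays in all.

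Single arrays held few values far from 0. If the deposited values are log2 ratios, 50 features lay beyond 2-fold on at least 1 of the 5 arrays and 0 on at least 2. CBFB, the non-DNA-binding partner of the RUNX transcription factors, had the lowest value, -3.32 on lymph 1, against 0.14, 0.35, 0.19 and 0.08 on adrenal 1, adrenal 3, lymph 2 and the shared array. RHOC, a small GTPase of the cytoskeleton, stood at -1.76 on lymph 1 and 0.21 on lymph 2. On adrenal 3, the ribosomal protein gene RPL27A stood at -1.70 and GOT2, the mitochondrial aspartate aminotransferase, at -1.41, against 0.02 and -0.08 on adrenal 1. PNMT, the enzyme that makes adrenaline from noradrenaline, stood at 1.499 on adrenal 1, had no value on adrenal 3, and stood at -0.18 and -0.22 on lymph 1 and 2. These genes were chosen after their values were seen.

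The number of features beyond 2-fold, on the log2 reading, was 6 on adrenal 1, 13 on adrenal 3, 30 on lymph 1, 0 on lymph 2 and 1 on the shared array. The share was 0.0497% ± 0.0260 in adrenal and 0.0789% ± 0.112 in lymph (SD, n = 2 each). If the values are log10 ratios, the shares become 7.01% and 7.50%. The SD of the log ratios was 0.147 and 0.181 on adrenal 1 and 3, 0.194 and 0.154 on lymph 1 and 2, and 0.0926 on the shared array. The mean SD was 0.164 ± 0.0238 in adrenal and 0.174 ± 0.0285 in lymph (n = 2 each), a difference of 0.010 that was smaller than the spread between arrays (exact permutation p = 0.667, with 0.333 the smallest possible).

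**Figure D1:**
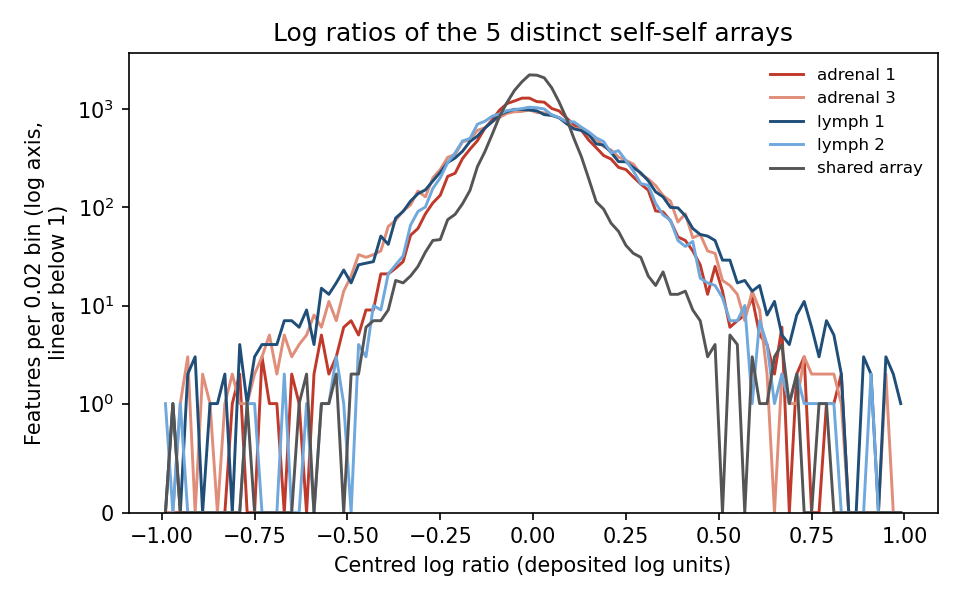
Number of features (log axis, linear below 1) in bins of 0.02 centred log units from -1 to 1, with 1 line for each of the 5 distinct arrays. The shared array is the narrowest, with an SD of 0.0926 against 0.147 to 0.194 on the others, and lymph 1 has the widest tails.

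In adrenal against adrenal, 0 of 18941 features differed from 0 with limma at an adjusted p under 0.05, and the smallest adjusted p was 0.559. An unadjusted p under 0.05 was reached by 1406 features, 1016 above 0 and 390 below, where 947 are expected by chance, and by 736 without adrenal 3. Among features of 1 named gene, the smallest p above 0 were those of UBE2E3, a ubiquitin-conjugating enzyme, at 0.48 ± 0.09 (SE, n = 2), PTGES3, the p23 co-chaperone of HSP90, at 0.46 ± 0.09, and ST7, SETD3 and GET3 at 0.48, 0.48 and 0.45. SETD3 methylates actin and GET3 is the ATPase that delivers tail-anchored proteins to membranes. Below 0 were ZMIZ2 at -0.55 ± 0.12, the kinetochore gene NUF2 at -0.83 ± 0.19, the leukocyte adhesion gene ICAM3 at -0.53 ± 0.12, GYG1, the primer of glycogen synthesis, at -0.35 ± 0.09, and LYRM2 at -0.35 ± 0.09. The largest differences between the 2 arrays among these 10 genes were those of ZMIZ2 at -0.81 on adrenal 1 and -0.28 on adrenal 3, NUF2 at -0.31 and -1.34, and ICAM3 at -0.79 and -0.26. The SE is limma's moderated one, drawn from both tissues and all features, so it does not measure the spread of these 2 arrays. Among unnamed features, number 12459 stood at 0.55 and number 757 at -0.64. Leaving out adrenal 1 or adrenal 3 gave 17 or 3 calls, since the remaining adrenal array then stood alone and was assumed to vary like the lymph arrays. With no filter on empty cells 1 feature was called, PNMT at 1.499 (limma adjusted p = 0.0379), whose only adrenal value was on adrenal 1. Over 19 alternatives the smallest adjusted p of any adrenal feature ranged from 0.00164 to 0.836.

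In lymph against lymph, 0 features differed from 0 with limma, with a smallest adjusted p of 0.400. An unadjusted p under 0.05 was reached by 1462 features, 985 above 0 and 477 below, where 947 are expected by chance. The number was lower without lymph 1 and higher without lymph 2, in fits that leave lymph with 1 array. CNTROB, a protein of daughter centrioles, stood at 0.74 ± 0.11 (SE, n = 2), EIF3I, a subunit of translation initiation factor 3, at 0.58 ± 0.09, and ARHGAP21 at 0.70 ± 0.11. The potassium channel gene KCND1 stood at 0.56 and MOGS, the first glucosidase of N-glycan trimming, at 0.55. Below 0 were the adiponectin receptor gene ADIPOR2 at -0.50 ± 0.11, TSPAN12 at -0.36, SEC23A, a coat protein of vesicles leaving the endoplasmic reticulum, at -0.44, NPNT at -0.34 and GRWD1 at -0.34. ADIPOR2 stood at -0.71 on lymph 1 and -0.29 on lymph 2, and SEC23A at -0.63 and -0.25. Unnamed feature 1 stood at 0.74 and unnamed feature 15978 at -0.52, with -0.79 on lymph 1 and -0.24 on lymph 2. Leaving out lymph 2 gave 5 calls, among them CBFB, ABR and RHOC, whose values came from lymph 1 alone.

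The difference between the tissues asked whether departures from 0 depended on the tissue. With limma, 0 features passed, the smallest adjusted p was 0.929, and 899 features had an unadjusted p under 0.05, where 947 are expected by chance. Without 1 array the number was 1154 (adrenal 1), 561 (adrenal 3), 840 (lymph 1) and 1518 (lymph 2). The mitochondrial ribosomal protein gene MRPS26 had the smallest p, with lymph minus adrenal at -0.75 ± 0.14 (SE) and values of 0.59 and 0.37 on the adrenal arrays and -0.37 and -0.18 on the lymph arrays. Other values below 0 were those of PTGES3 at -0.56, GDAP1L1 at -0.65, ALDH2, which oxidises acetaldehyde, at -0.58, and MEGF6 at -0.51. Above 0 were the phosphatase gene CTDSP1 at 0.58 ± 0.12, LYRM2 at 0.57 ± 0.12, GPS2, a subunit of the nuclear receptor corepressor complex, at 0.56 ± 0.12, ARHGAP21 at 0.68 ± 0.15 and DPYSL5 at 0.53 ± 0.12. With the shared array placed in lymph 0 features were called, and with the filter on empty cells dropped as well 1 was, PNMT at -1.63 (limma adjusted p = 0.0440), with its only adrenal value on adrenal 1. Leaving out adrenal 1, adrenal 3 or lymph 2 gave 8, 3 and 5 calls. Over 19 alternatives the smallest adjusted p of the difference ranged from 0.00591 to 0.999.

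In the average of the 5 distinct arrays, 0 features passed with limma (smallest adjusted p = 0.332), while 1843 had an unadjusted p under 0.05 against 947 expected, 1237 above 0 and 606 below. GPR137 stood at 0.28 ± 0.05 (SE, n = 5), the diacylglycerol lipase gene DAGLB at 0.31 ± 0.06, the fatty acid transporter gene SLC27A4 at 0.26 ± 0.05, CLINT1, a partner of clathrin, at 0.27 ± 0.05, and LOC786430 at 0.30 ± 0.05. Below 0 were SLC25A27, a mitochondrial carrier, at -0.22 ± 0.05, STAG3, a cohesin subunit of meiosis, at -0.24 ± 0.05, LOC518495 at -0.21, ZNF22 at -0.24 and FATE1 at -0.26. Each of these 10 genes lay on the same side of 0 on all 5 arrays, which is part of what a small p selects. Without lymph 2, 1 unnamed feature was called, number 500 at 0.65.

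The log ratios of different arrays were weakly correlated across features, which are not independent replicates. All 10 pairs of distinct arrays had a Pearson r above 0, from 0.0145 to 0.158 (Spearman correlation from 0.0197 to 0.173), with a mean of 0.0866, or 0.0564 without adrenal 1. The mean was 0.113 within tissues and 0.105 between them. This difference of 0.00807 was the largest of the 3 possible splits (exact permutation p = 0.333, one-sided, the smallest possible). It became -0.0598 without adrenal 3 and 0.0640 without lymph 2.

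**Figure D2:**
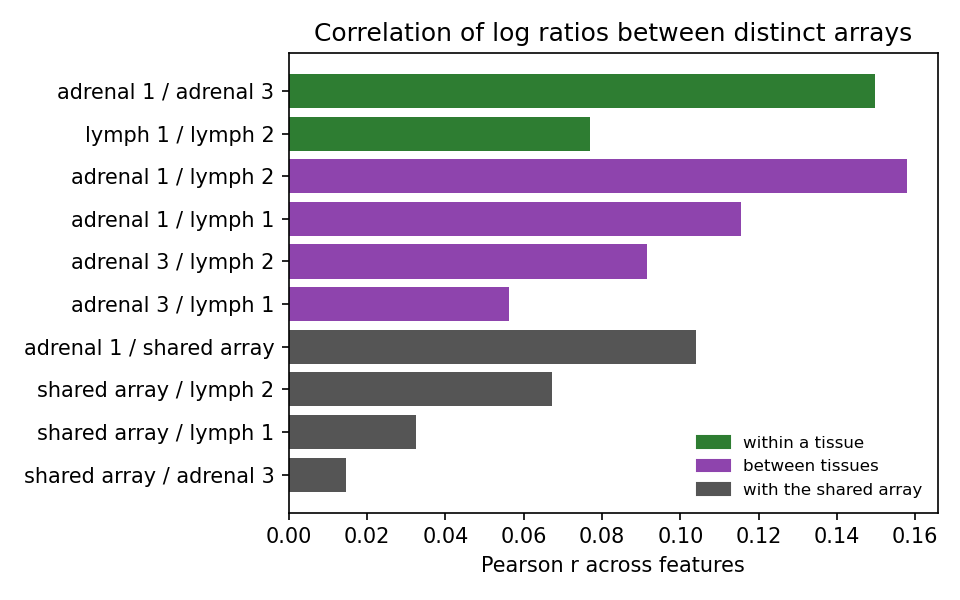
Pearson r across features for the 10 pairs of distinct arrays, coloured by whether the pair comes from 1 tissue, from both tissues or includes the shared array. All bars lie above 0, between 0.0145 and 0.158, and pairs from 1 tissue do not stand apart from pairs between tissues.

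Among the 13 gene lists, the cytosolic ribosomal proteins were the 1 list past camera's threshold, and they lay above all other genes. In the average of 5 arrays 39 of 51 ribosomal genes were above 0, with a median of 0.073 against 0.0049 for all genes (camera adjusted p = 3.70e-05, 0.640 with an estimated correlation). The median was 0.085 in adrenal, with 38 of 51 above 0 (adjusted p = 0.00189, 0.645 with an estimated correlation), and 0.060 in lymph, with 37 of 51 above 0 (adjusted p = 0.00664, 0.908 with an estimated correlation). None of these calls held with the estimated correlation. Fry asks whether the list moved and does not compare it with other genes. Its adjusted p was 0.113 for the average, 0.213 for adrenal and 0.207 for lymph. Before adjustment over the 13 lists, the fry p was 0.00866, 0.0491 and 0.0501. The estimated correlation in the adrenal and lymph tests was 0.0121, close to the preset value, and 0.0647 in that of the average. In adrenal and lymph the loss of the call therefore reflects mainly the 2 residual degrees of freedom, not the correlation. The adrenal call was also lost without adrenal 1 (adjusted p = 0.650), and the lymph call without lymph 1 (0.115) or lymph 2 (0.138). The call of the average, at the preset correlation, stayed with each of the 5 arrays left out (adjusted p from 1.37e-05 to 0.00122). Of the 51 genes, 0 passed over all genes tested in any of the 4 tests, and 7 passed adjusted over the list alone in the average.

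The ribosomal median lay above 0 on each of the 5 arrays, at 0.092 and 0.052 on adrenal 1 and 3, 0.054 and 0.059 on lymph 1 and 2, and 0.037 on the shared array. RPL38 had values from 0.096 to 0.73, RPS7 from 0.098 to 0.32 and RPL26 from 0.047 to 0.34 on the 5 arrays, and RPS15 lay at -0.14 on average. These examples were chosen after their values were seen. The list's mean exceeded that of all genes by 0.054 ± 0.033 (SD over 5 arrays, exact sign-flip permutation p = 0.0625, the smallest possible, Benjamini-Hochberg 0.813 over 13 lists). On adrenal 3 the excess was 0.016, within its standard error over genes of 0.043. RPL27A, a member of the list, stood at -1.70 on adrenal 3 and lowers this mean. The list's median on adrenal 3 was 0.052, against 0.0031 for all genes. The tissues did not differ by test in this list (camera adjusted p = 0.868). Its median difference of -0.034 and mean difference of 0.014 had opposite signs. The value of RPL27A on adrenal 3 raises the mean difference, so the opposite signs may rest on this 1 feature.

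The lists for the cells of the 2 tissues did not pass in any of the 4 tests. In adrenal against adrenal, the 18 genes of cortical steroid synthesis with values on all arrays had a median of -0.016 and the 15 chromaffin cell genes a median of 0.051 (camera adjusted p = 0.719 for each). Within the chromaffin list, CHGA, which codes for a granule protein, stood at -0.83 on adrenal 3 and -0.013 on adrenal 1, and the vesicular monoamine transporter gene SLC18A2 lay above 0 on all 5 arrays, from 0.11 to 0.26. In lymph against lymph, the 20 T and NK cell genes had a median of 0.042 (adjusted p = 0.233), the 14 B and plasma cell genes -0.012 (0.987), the 22 myeloid and antigen presentation genes -0.0084 (0.924), and the 12 stroma and chemokine genes 0.031 (0.678). CD8A, a co-receptor of cytotoxic T cells, lay above 0 on all 5 arrays, from 0.037 to 0.58. CHGA, SLC18A2 and CD8A were named outside the rule for named genes. CHGA lay below 0 on all 5 arrays, and 7.05% of 8315 genes lay above 0 on all 5. Adjusted over the list alone, 1 member passed for T and NK cells in adrenal and in the average, for stroma in lymph, and for chromaffin and myeloid cells in the average. Over all genes 0 passed.

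Of the lists for admixture and handling, connective tissue and endothelium had a median of 0.012 in the average of 5 arrays (camera adjusted p = 0.909), adipose, blood and muscle 0.0026 (0.960), heat shock and immediate early genes 0.0093 (0.960), and the cell cycle -0.0039 (0.909). Oxidative phosphorylation, with 46 of 69 genes above 0, had a median of 0.024 (0.433). The often-used reference genes had a median of 0.0034 (0.909), and lymph minus adrenal was above 0 in 10 of 14 of them, with a median over all 14 of 0.16 (adjusted p = 0.285, 0.872 with an estimated correlation).

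**Figure D3:**
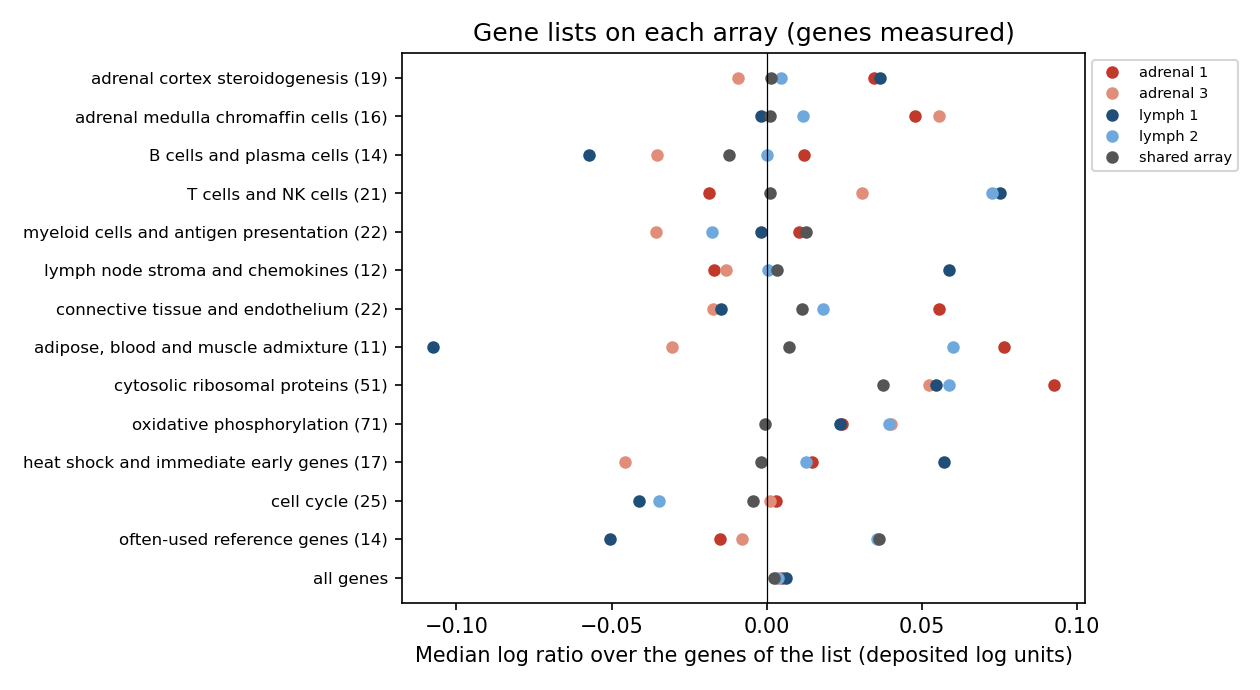
Median centred log ratio (deposited log units) of each gene list on each of the 5 distinct arrays, with the number of genes measured in brackets and all genes in the last line. The cytosolic ribosomal proteins lie above 0 on 5 of 5 arrays, from 0.037 to 0.092, and each other list lies on both sides of 0. All genes also lie above 0 on 5 of 5 arrays, from 0.0024 to 0.0062.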

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

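Several alternatives left the count of calls at 0 in all 4 comparisons, as in the results above. They were the values as deposited, scaling, features with a value on every array, other spread estimates, the unmoderated test and stricter thresholds. Gene averages, runs of 400 feature numbers and all 6 columns as designed did so too. So did, chosen after seeing the data, the shared array in adrenal or in lymph. Calls appeared with no filter on empty cells (1 in adrenal). With that filter dropped and, chosen after seeing the data, the shared array in lymph, there was 1 in adrenal and 1 in the difference; with it in adrenal, 0. Leaving out 1 array gave 0 to 17 calls in adrenal, 0 to 5 in lymph, 0 to 8 in the difference and 0 to 1 in the average. In the tissue comparisons this leaves a tissue with 1 array, where 1 value is then enough and whose extreme values are judged by the spread of the other tissue. NUF2 passed in this way at -1.34 (adjusted p = 0.00428). Features at an unadjusted p under 0.05 fell to 612, 667, 401 and 818 with gene averages, where fewer items were tested. They were 736 in adrenal and 561 in the difference without adrenal 3, and 1518 in the difference without lymph 2; the cause was not tested.

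Whether the replicate numbers pair the arrays could not be judged, since 1 column stands as both adrenal 2 and lymph 3. That column enters both tissue means, from which the correlations of deviations were 0.0757, -0.185 and -0.168 for numbers 1 to 3. With the replicate block on all 6 columns, 0 features passed in each comparison, and 484 features differed between tissues at an unadjusted p under 0.05, against 365 on those columns without it.

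The ribosomal call was the 1 list call in adrenal, lymph and the average, and it fell to 0 in each with an estimated correlation, and to a range of 0 to 1 in adrenal and lymph when 1 array was left out. In the average it stayed with each array left out. Fry, which asks another question, called 0 lists. The ribosomal call held with no centring and on single features. It also held on all 6 columns, where the shared array is entered under both tissues and so adds no independent array.

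On the log2 reading, the share beyond 2-fold became 0.400% in adrenal, 0.609% in lymph and 0.428% over the 5 arrays at 1.5-fold, and 0.00262% in adrenal and 0.0158% in lymph at 3-fold. In the mean of a tissue's arrays it was 0% in adrenal and 0.00526% in lymph. Read as natural logarithms the shares were 0.196%, 0.326% and 0.216%, and as log10 7.01%, 7.50% and 6.08%. The difference in spread ranged from -0.0102 to 0.0302, and that in correlation from -0.0598 to 0.0640, when 1 array was left out. The planned treatment of exact zeros as missing changed nothing, since there were 0. Signal over background was not used here, so its limits are unknown.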

Other observations

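Tests given only in this part were chosen after the results were seen, except the comparison of the ribosomal proteins with 2 other lists of the protein synthesis machinery, whose bounds were written before its result. RPL27A and GOT2, at -1.70 and -1.41 on adrenal 3, had neighbouring feature numbers, 18565 and 18566.

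Among 8 lists added after the data were seen, 28 splicing factors exceeded all genes on 5 of 5 arrays, by 0.016 ± 0.0065 (SD over 5 arrays, exact sign-flip permutation p = 0.0625, the smallest possible, Benjamini-Hochberg 0.375). On adrenal 1, adrenal 3, lymph 1 and the shared array the excess of the splicing factors was smaller than its standard error over genes. The 168 solute carriers lay above all genes on 1 of 5 arrays, at -0.013 ± 0.014. Proteasome subunits lay at 0.0093, zinc finger proteins at 0.0025, collagens at 0.0053 and potassium channels at -0.011.

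The spread changed along the feature numbers. Features 8001 to 11600, 18.8% of all, were picked out for their high SD on lymph 1. On that array they had 1.36 times the SD of the others and held 131 of its 177 empty cells. They also held 16 of its 30 features beyond 2-fold on the log2 reading. The SD ratio and the 2-fold count on lymph 1 are raised by this choice, so they are no test of the stretch. In the same stretch the ratio was 1.17 on adrenal 1, with 29 of 34 empty cells, and 1.08 on adrenal 3, with 14 of 85 empty cells. It was 1.01 on lymph 2 and 0.875 on the shared array. Also empty on lymph 1 were 24 of the 34 empty cells of adrenal 1 and 13 of the 85 of adrenal 3. The same held for 2 of 2 on lymph 2 and 1 of 6 on the shared array. The counts of empty cells are thus not independent of those on lymph 1. The first 696 features, which had no annotation entry, had 1.97 times the SD of the others on the shared array and 0.970 to 1.17 times on the other 4 arrays.

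The first pattern weighed is the identity of adrenal 2 and lymph 3. The most similar other pair of columns had equal values in 1 of 19200 rows, which argues against different hybridisations that agree by chance. A candidate explanation is that 1 array was entered under both tissues. Which tissue it held stays open. The shared array's mean correlation with the adrenal arrays exceeded that with the lymph arrays by 0.0094 (0.0593 against 0.0499). With all arrays kept, arrays of 1 tissue correlated better than arrays of different tissues by 0.00807. That lead could change sign when 1 array was left out, so an adrenal and a lymph origin cannot be told apart.

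The second pattern is the excess of features away from 0 in the average of 5 arrays, 1843 against 947 at an unadjusted p under 0.05. Features of the same gene were uncorrelated in that average (r = -0.00035, 5421 pairs in 3167 genes), and the upper 95% bootstrap limit of 0.0276 lay below 0.312, the share of the average's variance that repeated from array to array. This argues against a difference in gene-level RNA between the channels as the whole cause, provided that features of 1 gene report the same RNA, for which there was no positive control. The mean correlation of 0.105 between arrays of different tissues goes with effects tied to the feature, such as dye or probe, that both tissues share. These may account for part of the excess. Features with adjacent numbers also correlated weakly, at 0.049 to 0.058 on the single arrays and 0.075 in the average. At a distance of 400 the average gave 0.013. Part of the average thus followed the feature order, for a reason that was not tested. Centring within runs of 400 feature numbers left 1816 features, but cannot remove effects of shorter stretches. The real signs of 5 arrays gave 1840 features among the 18936 with a value on each, against at most 1494 under other sign patterns, and 1 of 16 patterns was as large. For the difference between tissues the real split gave 899 features and the highest other split 843, with 1 of 3 as large. Both sets are too few for a share under 0.05.

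The third pattern is the shift of the cytosolic ribosomal proteins. Its median was 0.073. Of the 51 genes, 14 were above 0 on all 5 arrays, against 7.05% of 8315 genes, and 1 was below 0 on all 5. These counts treat genes as independent. The list's call was lost with an estimated correlation of 0.0647 (adjusted p = 0.640). One hypothesis was a shift of all genes of the protein synthesis machinery. Mitochondrial ribosomal proteins exceeded all genes on 4 of 5 arrays, by 0.014 ± 0.018 (SD), and translation factors on 3 of 5, at -0.0017 ± 0.014. The bound written beforehand counted against the hypothesis if either list lay below all genes on at least 2 of 5 arrays. Translation factors met it, at -0.016 on adrenal 1 and -0.017 on lymph 2. These shortfalls were smaller than the standard errors over genes (0.019 and 0.026), a condition that was not in the bound. The bound thus went against the hypothesis, though shortfalls of this size decide little. No tissue explanation was tested beyond the list's difference between tissues, and the dyes and probe lengths were not used here.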
